A study of Mus musculus with 140 samples.

How the data were processed

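The data were the deposited expression values of 140 Affymetrix arrays, an A and a B array of the mouse 430 set for each of 70 RNA samples in 9 courses. Per the submitters' processing notes the authors computed signals with MAS5, whose version is not given in the sources used here. The deposited values were intensity on a linear scale, 1 per probe set and array. On every array the 2% trimmed mean of the 100 normalization control probe sets that both designs share was 2500, so arrays had been scaled on these controls. Samples were grouped by the course and day in the labels. A Dppa4 course was not analysed here, nor were a day 7 sample of the Mm343880 and retinoic acid courses and list genes that the annotation does not name.

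The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to have been made afterwards. Of 45265 probe sets 128 were controls, 35041 named 1 gene, 936 named several and 9160 named none. Signals were taken as log2(signal + pseudocount), with a pseudocount at the 20th percentile of each table (63.1 for A and 21.8 for B). Fold changes are on this scale, which understates the change of genes with low signals. A probe set was used where its signal was above the table median (283.3 for A and 89.2 for B) on at least 3 of the 70 arrays, which left 32992. Each gene was represented by the probe set with the highest mean percentile rank among those that name exactly 1 gene, giving 14749 genes, 7751 on A and 6998 on B.

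Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), separately for A and B, with a natural cubic spline of day with 3 degrees of freedom in each course. Late values were averages of the curves over days 4, 5 and 6, and early values over days 0 and 1. The late difference compared a knockdown course with the empty vector. The change over time compared late with early values within a course, and for knockdown courses also beyond the change of the empty vector. Both forms leave out an effect that was already complete on the early days. Direct differences compared late values of 2 knockdown courses. P-values were adjusted by Benjamini and Hochberg over both tables, with a threshold of 0.05. For target genes, day-matched differences from the empty vector were tested by an exact two-sided sign-flip permutation test. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 126 tests. Changes of the lists within each knockdown course, without the empty vector, were tested in the same way after the results were seen, adjusted over 98 tests.

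The text names the regulators of the study, the 6 largest rises and 6 largest falls per comparison that passed and had that sign on each of days 4, 5 and 6, and up to 4 passing members of each gene list, with up to 2 others. This gave 741 gene and comparison pairs, from which examples were taken. Of 500 other probe sets of these genes, 217 had a fold that differed by over 1.5 times and 1 passed in the opposite direction. The 14 lists covered pluripotency, LIF and Stat3, primed epiblast, trophectoderm, extraembryonic endoderm, mesoderm and streak, neuroectoderm, retinoic acid response, interferon response, p53 and apoptosis, mitotic cell cycle, hypoxia and glycolysis, fibroblast markers and germ line markers.

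Array medians ran from 236 to 383 on A and from 64.5 to 128.5 on B. Differences of the shared control probe sets between the A and B arrays of a sample gave an SD per array of 0.133 on the log2 scale. Arrays had been scaled on these same controls, so this may understate the technical spread. The highest correlation between any pair of arrays was 0.9665, so no array was counted as a copy of another. Between adjacent days of the empty vector course 336 to 795 genes were higher and 361 to 1163 lower by at least 2-fold. The models were tested on simulated data for the Nanog course with 14749 genes, of which 100 changed by log2 1 and 100 by log2 2. The late difference recovered 62% and 97% of them with 10 false calls, and the change beyond the empty vector 20% and 75% with 0 false calls. Alternatives were a pseudocount of 1 and of the table median, no filter, quantile normalization, all probe sets, the mean of all probe sets of a gene, a spline with 2 degrees of freedom, no spline, a fit of only the courses compared, eBayes without trend, and leaving out each day in turn. Array quality weights, leaving out the 3 arrays farthest from their curves and leaving out day 0 were chosen after seeing the data.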

Results

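Gene expression was followed in mouse embryonic stem cells of the CCE line while single regulators of self-renewal were knocked down by short hairpin RNA (shRNA). The 70 RNA samples formed 9 courses, and each sample was hybridised to an A and a B array, which gave 140 arrays. In 7 courses the cells carried an shRNA against Nanog, Oct4 (the product of Pou5f1), Sox2, Esrrb, Tbx3, Tcl1 or the transcript that the labels call Mm343880. An empty vector course was the reference, and in a further course cells received 5 µM retinoic acid without LIF (leukaemia inhibitory factor), the cytokine that keeps these cells undifferentiated. Transduced cells were kept in LIF at 1000 units/ml and sorted for GFP daily, with day 0 set 48 hours after transduction. The Mm343880 and retinoic acid courses ran from day 0 to day 6 (7 samples each) and the other courses from day 0 to day 7 (8 samples each). Each course had 1 sample per day and no replicate transductions, so p-values measure the spread of samples around smooth curves over days, part of which may be technical. The number of arrays limits the precision of every value. Median signal was 285 ± 32.2 (SD, n = 70) on A arrays and 90.0 ± 13.2 on B arrays. In the retinoic acid course it was 342 ± 40.2 on A arrays and 112 ± 12.0 on B arrays (SD, n = 7).

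The targeted gene was examined first, in every sample. Nanog signal was 1040 ± 251 (SD, n = 8 days) under Nanog shRNA against 7070 ± 559 in the empty vector course, 6.55-fold lower. Pou5f1 signal was 2620 ± 1340 under Oct4 shRNA against 15900 ± 1130, 6.53-fold lower, and Sox2 signal was 996 ± 519 under its shRNA against 4730 ± 963, 4.92-fold lower. Tcl1 signal was 3.40-fold lower under its own shRNA. Tbx3 signal was 7.80-fold lower on the probe set used for the gene and 3.24-fold lower on another. Esrrb signal was 2.63-fold lower on the probe set used for the gene, and 4.50-fold and 10.2-fold lower on others. On these probe sets the target was lower than in the empty vector on 8 of 8 days (exact two-sided sign-flip permutation p = 0.00781, the smallest that 8 days allow). For the 6 probe sets used for the genes the adjusted p was also 0.00781. A further Tbx3 probe set with a mean signal of 44.3 in the empty vector was lower on 7 of 8 days (exact permutation p = 0.0234). The log2 difference of Pou5f1 in its course was -3.16 on day 0 and -1.56 on day 7. The target of the Mm343880 shRNA was not analysed here.

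**Figure D1:**
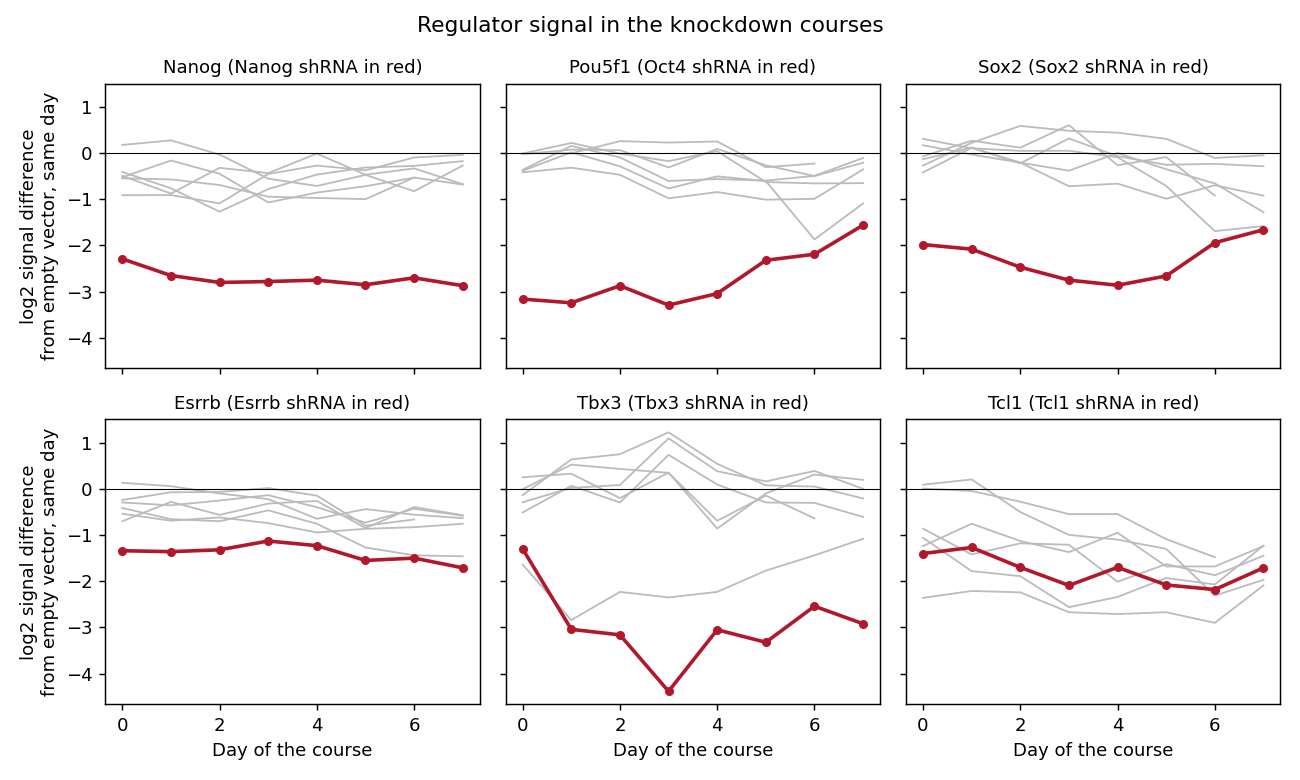
Signal of each targeted regulator in the knockdown courses, as the log2 difference from the empty vector on the same day (vertical axis) by day (horizontal axis), with 1 sample per point; the course that targeted the gene is red and the other knockdown courses are grey. The targeted gene lay below the empty vector on 8 of 8 days in each panel, and Tcl1 also lay low in courses that targeted other genes.

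The empty vector course showed how far transduced cells moved by themselves between days 0 and 1 and days 4 to 6. The list of p53 and apoptosis genes fell: of 15 measured members 5 fell and 0 rose (7 passed adjusted over the list alone; adjusted p = 9.23e-10, and adjusted p = 5.85e-06 with an estimated correlation). Plk2, a stress-induced kinase gene, fell by 1.84 ± 0.29 on the log2 scale (SE, adjusted p = 0.00052), from a signal of 2380 to 628. Trp53inp1, a p53 target, fell by 1.68 ± 0.33 (adjusted p = 0.0059). Without day 0 the changes were -2.20 ± 0.53 for Plk2 (adjusted p = 0.11) and -1.16 ± 0.61 for Trp53inp1 (adjusted p = 0.94), with larger errors. The keratin gene Krt18 rose 2.61-fold (log2 1.38 ± 0.27, adjusted p = 0.0052). Its change was 1.16 ± 0.50 without day 0 (adjusted p = 0.78) and 1.17 ± 0.29 without day 4 (adjusted p = 0.064). The regulators had changes between -0.26 (Dppa4) and 0.57 (Tcl1) that did not pass. Hypoxia and glycolysis genes (median log2 change 0.28, adjusted p = 0.0108), fibroblast markers (0.23, adjusted p = 0.0265) and extraembryonic endoderm genes (0.18, adjusted p = 0.0276) rose as lists, with adjusted p = 0.64, 0.232 and 0.408 with an estimated correlation. The hypoxia list had adjusted p = 0.12 after quantile normalization, and the fibroblast list 0.06 with the mean of all probe sets of a gene. In total 109 of 14749 genes changed (69 rose and 40 fell). Without day 0 the count was 6, and without day 1, 2, 4, 5 or 6 it was 38, 59, 40, 231 and 31. In the knockdown courses, rose and fell are used of late values against those of the empty vector, so a movement of the empty vector enters them.

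In the Nanog course, genes of the trophectoderm, the outer layer of the early embryo, rose on days 4 to 6 against the empty vector. Of 22 measured trophectoderm genes 19 rose and 0 fell (20 passed adjusted over the list alone; adjusted p = 2.47e-29). The homeobox gene Rhox6 rose 29.9-fold (log2 4.90 ± 0.22, SE), at 12700 ± 6500 against 343 ± 47 (SD, n = 3 days each). The epithelial keratin genes Krt19 and Krt7 rose 28.0-fold and 21.7-fold, and Krt18 rose by 4.32 ± 0.24 on the log2 scale. Outside the lists, Sct, which encodes the hormone secretin, rose 35.5-fold (adjusted p = 5.6e-17) and Ldoc1 24.9-fold. Among 30 pluripotency genes 17 fell and 1 rose (20 passed adjusted over the list alone; adjusted p = 9.14e-10). Nanog itself was 6.82-fold lower, Eras, a Ras gene of embryonic stem cells, 5.95-fold lower, and Prdm14, a regulator of the naive state, 3.03-fold lower. Among the other regulators Tcl1 was 2.94-fold lower, Esrrb 2.17-fold lower (2.39-fold and 3.84-fold on other probe sets), Pou5f1 1.96-fold lower and Sox2 1.71-fold lower, whereas Tbx3 did not pass (log2 -0.12 ± 0.27, adjusted p = 0.82). Outside the list, Prmt8, an arginine methyltransferase gene, was 11.4-fold lower and Inhbb, which encodes a subunit of activin and inhibin, 7.76-fold lower.

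Other gene groups also moved in the Nanog course. Extraembryonic endoderm genes rose in 9 of 24 cases and fell in 0 (10 passed adjusted over the list alone; adjusted p = 0.00011, and adjusted p = 0.0912 with an estimated correlation), among them the endocytic adaptor gene Dab2 (3.81-fold), the basement membrane collagen gene Col4a1 (2.97-fold) and the transcription factor gene Gata6 (2.30-fold). Mitotic and replication genes fell in 11 of 23 cases and rose in 0 (adjusted p = 0.00045, and adjusted p = 0.158 with an estimated correlation), including the replicative helicase genes Mcm3 (1.58-fold lower) and Mcm6 (1.57-fold lower). Among 19 hypoxia and glycolysis genes 5 were lower than in the empty vector, where this list rose (adjusted p = 0.00374, and adjusted p = 0.571 with an estimated correlation; 0.832 within the Nanog course), among them Hk2, which encodes hexokinase (2.27-fold lower), and Ldha, which encodes lactate dehydrogenase (1.92-fold lower). This list had adjusted p = 0.07 as a change over time beyond the empty vector. Among 15 p53 and apoptosis genes 7 were higher and 3 lower than in the empty vector, where this list fell (adjusted p = 0.0457, and adjusted p = 0.198 with an estimated correlation; 0.06 with the mean of all probe sets). Within the Nanog course the list did not pass (median log2 -0.31, adjusted p = 0.0755), but single members moved both ways. The cell cycle inhibitor gene Cdkn1a rose within it (log2 0.89, adjusted p = 0.000243). Gadd45a (log2 -1.68, adjusted p = 0.000139) and Zmat3 (-0.83, adjusted p = 0.000705) fell. Plk2 was 3.12-fold higher, at 2080 against 628, but at 2450 on days 0 and 1 of the Nanog course, and Mdm2, which encodes the ubiquitin ligase of p53, was 1.96-fold higher, at 1950 against 941, from 2410. Fibroblast markers did not shift as a list (adjusted p = 0.603): Tagln, an actin-binding protein gene of smooth muscle, rose 3.39-fold and the matrix gene Fn1 was 2.20-fold lower. The LIF and Stat3 list did not pass (adjusted p = 0.22), with Gbx2 3.75-fold lower. In all, 3059 genes differed (1644 higher and 1415 lower), 940 of them by at least 2-fold. After quantile normalization 1443 were higher and 1873 lower.

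The Oct4 course had a median log2 difference of 2.13 over the trophectoderm list, the largest of the 7 knockdown courses. Of the 22 genes 19 rose and 1 fell (21 passed adjusted over the list alone; adjusted p = 2.09e-38). Rhox6 rose 42.6-fold (log2 5.41 ± 0.22, SE), to 17100 ± 940 (SD, n = 3 days), the related homeobox gene Rhox9 27.2-fold and Krt19 27.7-fold. The imprinted growth factor gene Igf2 rose 26.0-fold and the transcriptional co-regulator gene Cited1 25.9-fold. Among 30 pluripotency genes 22 fell and 0 rose (22 passed adjusted over the list alone; adjusted p = 3.59e-19). Nr0b1, which encodes an orphan nuclear receptor, was 6.68-fold lower, the Nodal co-receptor gene Tdgf1 4.54-fold lower and Tcl1 4.30-fold lower. Pou5f1 was 5.74-fold lower on these days, Sox2 1.78-fold lower, Nanog 1.59-fold lower and Esrrb 1.45-fold lower (2.01-fold and 1.89-fold on other probe sets). Stmn2, a neuronal tubulin regulator, was 7.16-fold lower (adjusted p = 1.8e-16), and the primed epiblast genes Otx2 and Foxd3 were 4.05-fold and 3.36-fold lower. As lists, neuroectoderm (5 of 17 fell and 1 rose, adjusted p = 0.0714, and 0.042 after quantile normalization) and primed epiblast (5 of 13 fell and 2 rose, adjusted p = 0.0981) did not pass. Extraembryonic endoderm did not pass either (6 of 24 rose and 3 fell, adjusted p = 0.219): its median was -0.15 and its mean 0.15, and Pth1r, a parathyroid hormone receptor gene, rose 13.3-fold.

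Mitotic and replication genes fell in 7 of 23 cases in the Oct4 course (adjusted p = 0.00446, and adjusted p = 0.27 with an estimated correlation). Pcna, which encodes the replication clamp, was 1.56-fold lower. The p53 and apoptosis list had 15 genes, of which 5 were higher and 2 lower than in the empty vector, where this list fell (adjusted p = 0.0181, and adjusted p = 0.115 with an estimated correlation; 0.712 within the Oct4 course). Cdkn1a, which encodes the p21 cell cycle inhibitor, was 2.05-fold higher and Btg2 2.12-fold higher, and both also rose within the course (log2 0.55, adjusted p = 0.0353, and 0.99, adjusted p = 0.00688). Tagln (3.09-fold) and the smooth muscle actin gene Acta2 (2.11-fold) rose, while Fn1 was 2.06-fold lower, and the fibroblast list as a whole did not pass (adjusted p = 0.884). In total 2418 genes differed (909 higher and 1509 lower), 753 by at least 2-fold. After quantile normalization 1095 were higher and 1259 lower.

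The Sox2 course also raised trophectoderm genes: 19 of 22 rose and 1 fell (20 passed adjusted over the list alone; adjusted p = 5.93e-25). Rhox6 rose 34.5-fold (log2 5.11 ± 0.22, SE), Krt19 32.6-fold and the cell cycle inhibitor gene Cdkn1c 22.3-fold, to 12600 ± 1300 (SD, n = 3 days). Among 30 pluripotency genes 23 fell and 0 rose (25 passed adjusted over the list alone; adjusted p = 9.95e-19). Tcl1 was 6.72-fold lower and Sox2 itself 5.73-fold lower, and Eras and Nr0b1 were 4.74-fold and 4.52-fold lower. Dppa4 was 2.15-fold lower, Pou5f1 1.95-fold lower, Nanog 1.83-fold lower and Esrrb 1.83-fold lower (2.68-fold and 3.76-fold on other probe sets). Outside the lists, the amino acid transporter gene Slc7a3 was 10.9-fold lower and Trh, which encodes thyrotropin-releasing hormone, 10.7-fold lower. Tagln rose 15.5-fold, Acta2 6.47-fold and the collagen gene Col1a2 2.26-fold. Of 15 fibroblast markers 5 rose and 1 fell (adjusted p = 0.0391, and adjusted p = 0.27 with an estimated correlation).

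Cell cycle genes fell in the Sox2 course: 15 of 23 mitotic and replication genes were lower and 0 higher (adjusted p = 8.48e-07, and adjusted p = 0.036 with an estimated correlation), with Mcm2 1.91-fold lower. Among 15 p53 and apoptosis genes 8 were higher and 1 lower than in the empty vector, where this list fell (adjusted p = 0.000811, and adjusted p = 0.0209 with an estimated correlation; 0.701 within the Sox2 course). Plk2 was 3.87-fold higher, at 2500 against 628, from 2200 on days 0 and 1 of the Sox2 course. Cdkn1a was 2.73-fold higher and Perp, a p53 target of cell adhesion, 2.13-fold higher, and neither passed within the course (adjusted p = 0.219 and 0.606). Cdkn1a was, however, already higher on days 0 and 1 of the Sox2 course, at 3950 against 2252 in the empty vector. Within the empty vector course it changed little (log2 -0.20, adjusted p = 0.675). Hypoxia and glycolysis genes, whose list rose in the empty vector, were lower in 7 of 19 cases and higher in 1 (adjusted p = 0.00368, and adjusted p = 0.571 with an estimated correlation; 0.276 within the Sox2 course), with the kinase gene Pdk1 2.32-fold lower. Genes tied to retinoic acid moved both ways: the transglutaminase gene Tgm2 rose 5.64-fold and the binding protein gene Crabp2 3.76-fold, while Crabp1 was 5.99-fold lower, and the list did not pass (adjusted p = 0.473). The imprinted genes Dlk1 and Nnat rose 4.70-fold and 3.49-fold. The count of 3363 genes (1657 higher and 1706 lower, 1066 by at least 2-fold) was the largest of the 7 courses.

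In the Esrrb course pluripotency genes fell: 17 of 30 were lower and 0 higher (23 passed adjusted over the list alone; adjusted p = 1.77e-16). Esrrb itself was 2.68-fold lower on the probe set used for the gene and 4.38-fold and 9.45-fold lower on others. Tbx3 was 3.43-fold lower (2.93-fold on another probe set, and log2 -0.19 on one that did not pass), Tcl1 3.39-fold lower, Nr0b1 3.27-fold lower and the growth factor gene Fgf4 3.02-fold lower. Pou5f1 (log2 -0.44), Sox2 (-0.38) and Nanog (-0.29) did not pass (adjusted p = 0.081, 0.14 and 0.27). Khdc3, a gene of oocytes and early embryos, was 12.4-fold lower (log2 -3.63 ± 0.17, SE), at 325 ± 43 against 4270 ± 130 (SD, n = 3 days each). Of 22 trophectoderm genes 12 rose and 1 fell (15 passed adjusted over the list alone; adjusted p = 1.79e-10), including Krt19 (15.6-fold) and Krt18 (10.7-fold). The skeletal muscle actin gene Acta1 rose 15.2-fold, Tagln 14.9-fold and Acta2 8.87-fold. Among 15 fibroblast markers 7 rose and 1 fell (9 passed adjusted over the list alone; adjusted p = 5.96e-05, and adjusted p = 0.0181 with an estimated correlation), including Col1a2 (4.15-fold) and Col5a1 (2.13-fold). The neuropeptide precursor gene Vgf rose 18.9-fold and the signalling factor gene Fgf8 6.04-fold.

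Primed epiblast genes rose in 4 of 13 cases in the Esrrb course (adjusted p = 0.019, and adjusted p = 0.108 with an estimated correlation), among them the tight junction gene Cldn6 (3.03-fold) and the DNA methyltransferase gene Dnmt3b (1.54-fold). This list ran the other way within the Esrrb course (median log2 -0.41, adjusted p = 0.00504) and as a change over time beyond the empty vector (-0.31, adjusted p = 0.01). Among 15 p53 and apoptosis genes 5 were higher than in the empty vector, where this list fell (adjusted p = 0.025, and adjusted p = 0.141 with an estimated correlation; 0.286 within the Esrrb course). Plk2 was 3.43-fold higher, at 2370 against 628, from 2420 on days 0 and 1 of the Esrrb course. Germ line genes fell in 2 of 9 cases (adjusted p = 0.025, and adjusted p = 0.0912 with an estimated correlation; 0.069 after quantile normalization, 0.76 beyond the empty vector and 0.832 within the course), with Kit, the stem cell factor receptor, 2.39-fold lower. Altogether 1767 genes differed (1037 higher and 730 lower), 1128 without Esrrb day 5 and 1093 without a spline.

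The Tbx3 course lowered 5 of 30 pluripotency genes and raised 0 (7 passed adjusted over the list alone; adjusted p = 0.00022, and adjusted p = 0.0403 with an estimated correlation). Tbx3 itself was 8.47-fold lower (3.10-fold on another probe set, and log2 -0.64 on one that did not pass), Tcl1 2.78-fold lower and Eras 2.52-fold lower. The list did not pass as a change over time beyond the empty vector (median log2 -0.09, adjusted p = 0.3). Esrrb was 1.45-fold lower (adjusted p = 0.0027, and 0.14 without Tbx3 day 5) and 1.84-fold and 1.92-fold lower on other probe sets, and Pou5f1, Sox2 and Nanog did not pass (log2 -0.25, 0.21 and -0.23). Khdc3 was 5.82-fold lower (log2 -2.54 ± 0.17, SE). The chromatin remodeller gene Chd7 rose 10.0-fold, Krt19 9.13-fold, the amyloid precursor gene App 8.98-fold and the immunoproteasome gene Psmb8 6.55-fold, to 612 ± 27 against 39.9 ± 14 (SD, n = 3 days each). Of 22 trophectoderm genes 8 rose and 2 fell (adjusted p = 0.00124, and adjusted p = 0.0912 with an estimated correlation). The median of that list was 0.09 and its mean 0.51, with Krt18 at 5.04-fold.

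Primed epiblast genes rose in 3 of 13 cases in the Tbx3 course (adjusted p = 0.00374, and adjusted p = 0.0403 with an estimated correlation), Cldn6 by 3.36-fold. Within the Tbx3 course this list ran the other way (median log2 -0.65, adjusted p = 4.24e-05), and also as a change over time beyond the empty vector (-0.45, adjusted p = 0.00087). Among 15 p53 and apoptosis genes 5 were higher and 1 lower than in the empty vector, where this list fell (adjusted p = 0.000811, and adjusted p = 0.0209 with an estimated correlation; 0.305 within the Tbx3 course). Plk2 was 3.18-fold higher, at 2300 against 628, from 2170 on days 0 and 1 of the Tbx3 course. Of 15 fibroblast markers 5 rose and 2 fell (adjusted p = 0.041, and adjusted p = 0.27 with an estimated correlation; 0.18 beyond the empty vector), with Tagln at 4.57-fold, Acta2 at 3.39-fold and Col1a2 at 3.27-fold. In total 1611 genes differed (828 higher and 783 lower), 823 without Tbx3 day 5 and 815 without a spline. Quantile normalization turned this balance, with 807 higher and 839 lower.

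In the Tcl1 course Acta1 rose 11.9-fold, Tagln 10.2-fold and Acta2 7.52-fold (log2 2.91 ± 0.28, SE), to a signal of 13000 ± 2100 (SD, n = 3 days). The annexin genes Anxa1 and Anxa3, which encode membrane-binding proteins, rose 7.46-fold and 7.04-fold. Of 15 fibroblast markers 3 rose and 1 fell (adjusted p = 0.0191, and adjusted p = 0.198 with an estimated correlation; 0.054 with the mean of all probe sets and 0.18 beyond the empty vector). Pluripotency genes fell in 6 of 30 cases and rose in 0 (11 passed adjusted over the list alone; adjusted p = 0.00374, and adjusted p = 0.125 with an estimated correlation; 0.75 beyond the empty vector and 0.116 within the course), with Tcl1 4.04-fold lower and Klf2, a factor of the naive state, 2.14-fold lower. Pou5f1 was 1.51-fold lower (adjusted p = 0.019), with adjusted p = 0.062 without empty vector day 5, 0.063 without empty vector day 6, 0.051 without Tcl1 day 4 and 0.057 without Tcl1 day 5. Sox2 and Nanog did not pass (log2 -0.17 and -0.33), and Esrrb was 1.43-fold lower (adjusted p = 0.0047, and 0.093 without Tcl1 day 5) and 1.59-fold and 1.79-fold lower on other probe sets.

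Primed epiblast genes rose in 4 of 13 cases in the Tcl1 course (6 passed adjusted over the list alone; adjusted p = 8e-06, and adjusted p = 0.00091 with an estimated correlation): Cldn6 rose 2.68-fold, Sall2 2.07-fold and Dnmt3b 2.02-fold. Of 22 trophectoderm genes 8 rose and 2 fell (16 passed adjusted over the list alone; adjusted p = 1.13e-05, and adjusted p = 0.0174 with an estimated correlation), with Krt18 at 5.01-fold. Of the 15 p53 and apoptosis genes 4 were higher than in the empty vector, where this list fell (adjusted p = 0.000143, and adjusted p = 0.00949 with an estimated correlation; 0.06 within the Tcl1 course). Plk2 was 2.86-fold higher, at 1850 against 628, from 2180 on days 0 and 1 of the Tcl1 course. Tgm2 and Crabp1, genes of the retinoic acid list, were 2.59-fold and 2.08-fold lower, and the list did not pass (adjusted p = 0.52). The count of 1261 genes (691 higher and 570 lower) was the smallest of the 7 courses, and it was 632 without Tcl1 day 5 and 618 without a spline.

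In the Mm343880 course Tagln rose 13.7-fold, Acta1 12.6-fold, Acta2 9.81-fold and Cnn1, which encodes calponin, 10.3-fold (log2 3.36 ± 0.32, SE, adjusted p = 6.2e-10). Another probe set of Acta2 ran the other way (log2 -1.26, adjusted p = 0.038). Of 15 fibroblast markers 4 rose and 1 fell (adjusted p = 0.025, and adjusted p = 0.221 with an estimated correlation). Among 30 pluripotency genes 11 fell and 1 rose (15 passed adjusted over the list alone; adjusted p = 1.5e-05, and adjusted p = 0.0174 with an estimated correlation), with Prdm14 2.54-fold lower and Tcl1 2.09-fold lower. Nanog was 1.68-fold lower (adjusted p = 0.00098, and 0.54 without Mm343880 day 6), and Pou5f1 (log2 -0.10) and Sox2 (-0.36) did not pass. Of 22 trophectoderm genes 8 rose and 2 fell (adjusted p = 0.000849, and adjusted p = 0.0877 with an estimated correlation), with Krt18 at 6.26-fold and Krt8 at 5.27-fold. Among 15 p53 and apoptosis genes 7 were higher than in the empty vector, where this list fell (adjusted p = 1.5e-05, and adjusted p = 0.00212 with an estimated correlation; 0.0973 within the Mm343880 course). Plk2 was 3.43-fold higher, at 2220 against 628, from 3800 on days 0 and 1 of the Mm343880 course, and Perp was 2.48-fold higher (adjusted p = 0.278 within the course). Primed epiblast genes rose in 4 of 13 cases (adjusted p = 0.025, and adjusted p = 0.125 with an estimated correlation), Dnmt3b by 1.92-fold. Psmb8 rose 3.84-fold, and Ccnb1ip1, a gene of meiotic recombination, was 3.80-fold lower. The count of 2062 genes (1053 higher and 1009 lower) was 633 without Mm343880 day 6, 1240 without its day 5 and 1055 without a spline. Quantile normalization turned this balance, with 955 higher and 1219 lower. The log2 ratio of 3' to 5' Gapdh control signal, which can shift with RNA quality, also differed. On B arrays of days 4, 5 and 6 it was 0.080, -0.105 and -0.024, against -0.293, -0.286 and -0.229 in the empty vector. The actin ratio on A arrays was 0.278, 0.145 and 0.128 against 0.090, 0.104 and 0.167. Whether this affected the differences was not tested.

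**Figure D2:**
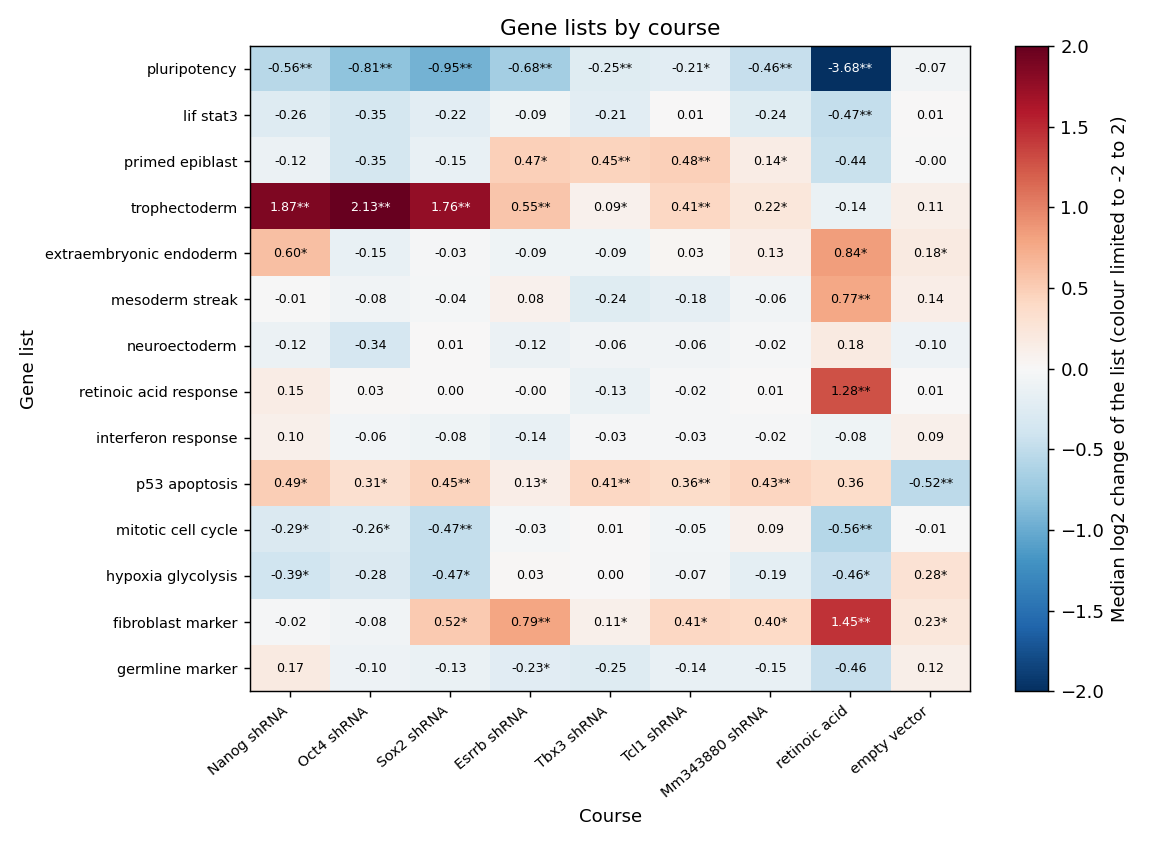
Median log2 change of each of 14 gene lists (vertical axis) in each course (horizontal axis), as the late difference from the empty vector for knockdown courses and as the change over time for retinoic acid and the empty vector; 1 asterisk marks a list past adjusted p 0.05 with the preset correlation and a pair of asterisks one that also passed with an estimated correlation. The trophectoderm median was 1.87, 2.13 and 1.76 in the Nanog, Oct4 and Sox2 courses, and the pluripotency median was -3.68 in the retinoic acid course.

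In the retinoic acid course, without LIF, nearly the whole pluripotency list fell between days 0 and 1 and days 4 to 6: 28 of 30 genes fell and 0 rose (29 passed adjusted over the list alone; adjusted p = 1.63e-48). Dppa5a was 60.7-fold lower (log2 -5.92 ± 0.14, SE), Nanog 37.5-fold lower and Sox2 10.3-fold lower, and Dppa4 fell by 3.81 ± 0.11 on the log2 scale. Pou5f1 was 53.8-fold lower, at 104 ± 91 (SD, n = 3 days) against 9070 ± 3100 (n = 2 days). Retinoic acid response genes rose in 15 of 22 cases and fell in 2 (17 passed adjusted over the list alone; adjusted p = 2.09e-05, and adjusted p = 0.0174 with an estimated correlation): the receptor gene Rarb rose 12.8-fold, Cyp26b1, which encodes an enzyme that degrades retinoic acid, 11.6-fold, and the homeobox gene Meis2 7.52-fold. Mesoderm and streak genes rose in 7 of 18 cases (adjusted p = 0.00135, and adjusted p = 0.0345 with an estimated correlation), including Snai2 (15.5-fold), Hand2 (10.0-fold) and Twist1 (9.14-fold). Among 15 fibroblast markers 8 rose and 0 fell (adjusted p = 0.000298, and adjusted p = 0.0345 with an estimated correlation), with the collagen genes Col3a1 at 57.1-fold and Col1a2 at 9.48-fold and periostin, Postn, at 14.9-fold. Extraembryonic endoderm genes rose in 15 of 24 cases and fell in 1 (adjusted p = 0.000103, and adjusted p = 0.0912 with an estimated correlation), Gata6 by 7.78-fold. The extracellular matrix gene Ecm1 rose 63.7-fold and Igf2 40.6-fold. Day 1 was part of the early reference, although Nanog signal was 6545 on day 0 and already 2523 on day 1. By then 2002 genes were higher and 995 lower than in the empty vector by at least 2-fold, against 406 and 793 on day 0. The changes given for this course may therefore understate the response.

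Cell cycle genes fell in the retinoic acid course, 13 of 23 (adjusted p = 1.01e-08, and adjusted p = 0.0174 with an estimated correlation), with Cdc20, which encodes an activator of the anaphase-promoting complex, 2.39-fold lower. Hypoxia and glycolysis genes fell in 8 of 19 cases and rose in 3 (adjusted p = 0.0153, and adjusted p = 0.646 with an estimated correlation), with the glucose transporter gene Slc2a1 3.84-fold lower. Genes of the LIF and Stat3 list fell in 7 of 14 cases and rose in 2 (adjusted p = 0.00588, and adjusted p = 0.03 with an estimated correlation), Gbx2 being 12.0-fold lower. The trophectoderm list moved both ways (8 of 22 rose and 5 fell, adjusted p = 0.653), with a median of -0.14 and a mean of 0.49, and Krt19 rose 14.5-fold and Gata3 4.99-fold. Neuroectoderm did not pass as a list (5 of 17 rose and 4 fell, adjusted p = 0.473), with Dlk1 and Sox11 at 41.2-fold and 10.7-fold and Stmn2 11.9-fold lower. Primed epiblast genes (4 of 13 rose and 4 fell, adjusted p = 0.184) and interferon response genes (4 of 14 fell, adjusted p = 0.284) did not pass either. The p53 list (5 of 15 rose, adjusted p = 0.108) and the germ line list (3 of 9 fell, adjusted p = 0.0647) did not pass, and had adjusted p = 0.026 and 0.045 after quantile normalization. In all 4734 genes changed (2644 rose and 2090 fell), 2205 by at least 2-fold. After quantile normalization 2065 rose and 2658 fell, and the median of all genes was -0.06 in place of 0.12, a shift of -0.18. The count was 2325 without retinoic acid day 0 and 1993 without its day 6, and 7296 genes differed from the empty vector on days 4 to 6. No sample separated the retinoic acid from the absence of LIF.

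Across the 7 knockdown courses, pluripotency genes passed as a list downward in 7 (medians from -0.95 to -0.21). Trophectoderm genes (medians from 0.09 to 2.13) and p53 genes (0.13 to 0.49) passed upward in 7. In the Tbx3 and Tcl1 courses the 4 passing trophectoderm members with the largest differences were the keratin genes Krt18, Krt19, Krt7 and Krt8. Primed epiblast genes passed upward in 4, fibroblast markers upward in 5, mitotic genes downward in 3, hypoxia genes downward in 2, extraembryonic endoderm genes upward in 1 and germ line genes downward in 1. The p53 list fell in the empty vector itself, and within the 7 knockdown courses it passed in 0 (medians from -0.31 to 0.03, lowest adjusted p = 0.06). Cdkn1a of this list already differed on days 0 and 1 in some courses. It was at 1720 in Nanog, from which it rose to 3400 on days 4 to 6. Against 2252 in the empty vector it was at 3950 in Sox2, 3270 in Tcl1 and 3170 in Mm343880. Tests within a course leave out such early differences. These tests of changes within a course, chosen after the results were seen, passed in the direction of the late difference for trophectoderm genes in 7 of 7 courses, pluripotency genes in 6 of 7, fibroblast markers in 5 of 5, mitotic genes in 3 of 3, extraembryonic endoderm genes in 1 of 1, primed epiblast genes in 2 of 4, hypoxia genes in 0 of 2 and germ line genes in 0 of 1. The median of pluripotency genes within the Tbx3 course was 0.07 although the test passed downward. Within the 7 courses, list tests passed upward for fibroblast markers in 6, extraembryonic endoderm genes in 5 and primed epiblast genes in 2. Hypoxia, neuroectoderm and mesoderm genes did so in 1 each. Mitotic genes passed downward in 5 and primed epiblast genes in 3. With an estimated correlation, 7 trophectoderm, 5 pluripotency, 5 fibroblast, 4 primed epiblast, 1 mitotic, 1 extraembryonic endoderm and 1 neuroectoderm tests within courses held. With an estimated correlation the late differences of pluripotency genes passed in 6, trophectoderm genes in 5, p53 genes in 4, primed epiblast genes in 2, fibroblast markers in 1 and mitotic genes in 1. As late differences, the retinoic acid response, interferon response, neuroectoderm, mesoderm and LIF and Stat3 lists passed in 0, with lowest adjusted p = 0.473, 0.559, 0.0714, 0.537 and 0.22. Of all 126 list and course tests 49 passed with the preset correlation and 26 of these with an estimated one. In 27 tests the median, mean and test of a list differed in sign, and 0 of these passed. Further lists passed under another setting only. After quantile normalization these were hypoxia genes in Mm343880 (adjusted p = 0.047) and mitotic genes in the empty vector (0.02). With the mean of all probe sets they were hypoxia genes in Mm343880 (0.041), germ line genes in the retinoic acid course (0.027) and trophectoderm genes in the empty vector (0.044). As changes over time beyond the empty vector they were hypoxia genes in Oct4 (median log2 -0.41, adjusted p = 0.012), primed epiblast genes (-0.66, 0.0027) and neuroectoderm genes (0.28, 0.0077) in Sox2, and mitotic genes in Mm343880 (-0.17, 0.0077).

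Changes over time beyond those of the empty vector leave out effects already complete on days 0 and 1. On day 0 the log2 difference of the target was already -2.29 for Nanog, -3.16 for Pou5f1 and -1.4 for Tcl1. They also leave out a constant offset between courses. Low counts therefore cannot tell late differences that arose early from such an offset. Changes beyond the empty vector were found for 472 genes in the Nanog course (317 up and 155 down), 180 in Oct4 (106 and 74), 366 in Sox2 (231 and 135), 209 in Esrrb (173 and 36), 73 in Tbx3 (65 and 8), 18 in Tcl1 (13 and 5) and 159 in Mm343880 (120 and 39). After quantile normalization the split was 296 and 244 in Nanog, 16 and 6 in Tbx3 and 70 and 49 in Mm343880, and the median of all genes moved by -0.12 in Esrrb, -0.14 in Tbx3 and -0.13 in Mm343880. Over the other settings, apart from single days left out, the counts ranged from 129 to 621 in Nanog, 33 to 275 in Oct4, 46 to 600 in Sox2, 34 to 289 in Esrrb, 2 to 1112 in Tbx3, 2 to 42 in Tcl1 and 18 to 469 in Mm343880. Without a spline they were 160, 33, 53, 34, 2, 2 and 18, and array quality weights, chosen after seeing the data, gave the 1112 in Tbx3. Without empty vector day 0 the counts were 91, 36, 44, 14, 2, 3 and 5 in the same order, and without the course's own day 0 they were 85, 37, 88, 38, 11, 9 and 23. Other single days also moved them over 1.5-fold. Without empty vector day 1 the count was 108 in Oct4 and 8 in Tcl1, and without its day 5 it was 27 in Tbx3. In Sox2 it was 208 without Sox2 day 1 and 240 without day 5. In Esrrb it was 126 without Esrrb day 5, in Tbx3 30 without Tbx3 day 1 and 30 without day 5, and in Mm343880 373 without its day 4 and 88 without day 5. In Tcl1 it was 4, 9, 11 and 2 without Tcl1 days 1, 2, 3 and 5, and 9, 11, 5 and 11 without empty vector days 2, 3, 4 and 6.

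**Figure D3:**
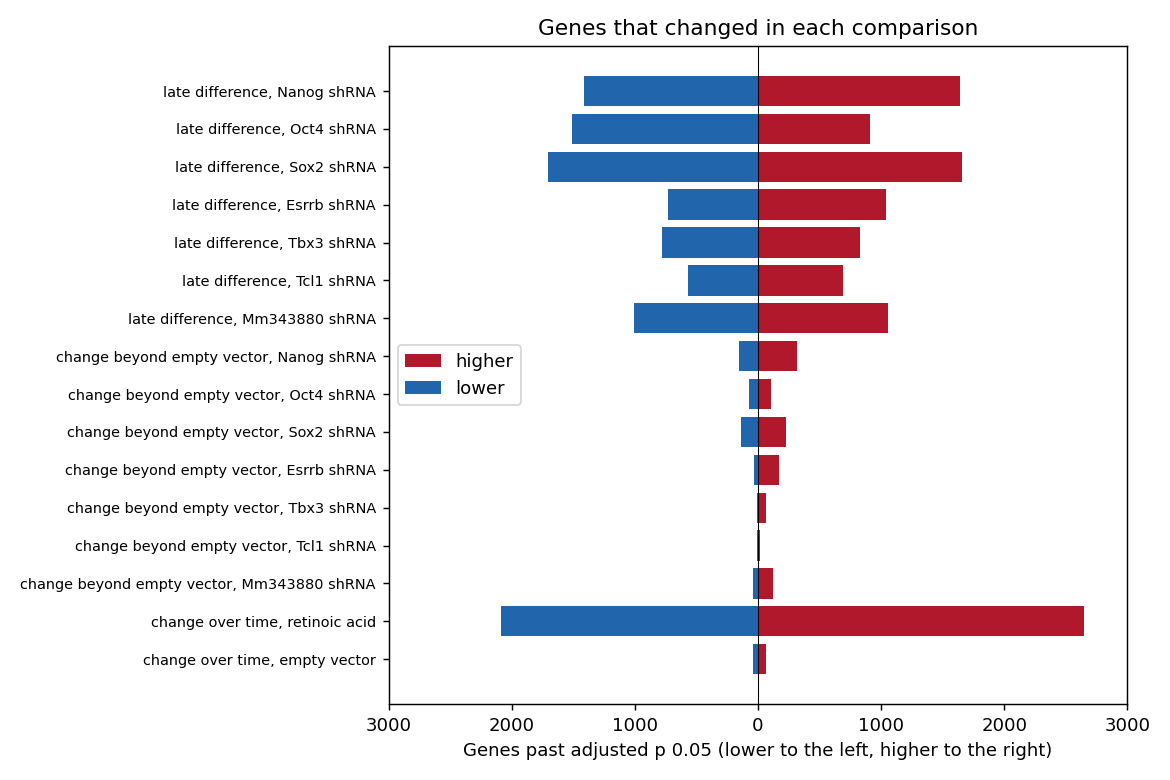
Number of genes past adjusted p 0.05 (horizontal axis, higher in red to the right and lower in blue to the left) in each comparison (vertical axis), of 14749 genes tested. Late differences ranged from 1261 genes (Tcl1) to 3363 (Sox2), and changes beyond the empty vector from 18 (Tcl1) to 472 (Nanog).

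The knockdown courses were then compared directly on days 4 to 6. The trophectoderm list had a median 1.60 higher on the log2 scale under Oct4 shRNA than under Tbx3 shRNA, and 1.78 higher under both Nanog and Sox2 shRNA than under Tbx3 shRNA. Over the 21 pairs the median count was 2207 genes. Esrrb and Tbx3 differed least, in 371 genes (267 higher and 104 lower under Esrrb shRNA), and had the lowest count of the pairs under every other setting in which all pairs were compared (not with single days left out), with 783 for a spline of 2 degrees of freedom, 71 without a spline and 233 in a fit of only these courses. It was 138 without Esrrb day 5 and 205 and 200 without Tbx3 day 4 and day 5. Sox2 and Tcl1 had the highest count, 3043, but under 4 other settings Sox2 and Tbx3 or Oct4 and Tbx3 did. Nanog and Oct4 differed in 1717 genes (1189 higher and 528 lower under Nanog shRNA), Nanog and Sox2 in 1534 (822 and 712) and Oct4 and Sox2 in 1085 (373 and 712). Quantile normalization gave 746 and 899, 714 and 943, and 510 and 563 for these pairs, and moved the median difference between Nanog and Oct4 by -0.14. Without Nanog day 5 the Nanog pairs gave 1073 (with Oct4) and 822 (with Sox2). Without Oct4 day 5 the Oct4 pairs gave 1112 (with Nanog) and 625 (with Sox2), and without Sox2 day 5 Nanog and Sox2 gave 984.

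Many genes moved alike in several courses. The Nanog, Oct4 and Sox2 courses shared 537 raised and 597 lowered genes, where independent lists would share 11.4 and 16.8. In all 7 courses 128 genes were raised and 63 lowered against the empty vector, where independent lists would share 0.00015 and 0.000116. Without the spline the counts in all 7 were 68 and 20. All these comparisons used the same empty vector samples. Late differences correlated across genes by 0.418 (Oct4 and Tbx3) to 0.739 (Oct4 and Sox2) in Pearson's r, unchanged groups simulated against those controls gave 0.498, and courses compared against separate control days gave 0.249 to 0.569. Genes are not independent replicates in these correlations. The covariance exceeded the simulated 0.041 by 0.0587 (Oct4 and Tbx3) to 0.201 (Nanog and Sox2). The simulation held no offset between courses, and the separate control days came from the same empty vector course. Neither therefore removes an offset of that course, which all these comparisons share. Changes within each course, which need no shared control, correlated across genes with a median of 0.362 over the 21 knockdown pairs (jackknife SE over days 0.0639, range 0.22 to 0.505). With the empty vector's own change the range was 0.14 to 0.256, and with that of retinoic acid 0.117 to 0.344.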

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

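The regulators and array measures searched for samples apart, and the comparison of gene lists between courses, were chosen after the data were seen. Of 90 groups of samples 10 held a sample far from the others. For exchangeable samples chance gives about 1 in 20 groups, or 4.5, but the days of a course are not exchangeable. A trend over days can set day 0 apart, so a sample named here need not be faulty. Nanog signal on day 0 was 8314 in the empty vector, 1644 under Nanog shRNA and 6545 with retinoic acid. Sox2 signal on day 0 was 7375 under Nanog shRNA and 6700 under Oct4 shRNA. Esrrb signal was 865.1 under Esrrb shRNA on day 4 and 1265 with retinoic acid on day 0. Tbx3 signal was 651.9 under Tbx3 shRNA on day 0. Tcl1 signal was 847.8 under Sox2 shRNA on day 7 and 1843 with retinoic acid on day 0.

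Gene lists differed between knockdown courses in 43 of 294 tests of the difference itself, given here as median log2 differences on days 4 to 6. For trophectoderm genes (adjusted p from 9e-11 to 0.042) Nanog shRNA exceeded Esrrb by 0.99, Tbx3 by 1.78, Tcl1 by 1.51 and Mm343880 by 1.56. Oct4 shRNA exceeded them by 0.959, 1.6, 1.7 and 1.5, and Sox2 shRNA by 0.983, 1.78, 1.53 and 1.44. Esrrb shRNA exceeded Tbx3 by 0.628, Tcl1 by 0.688 and Mm343880 by 0.542. For pluripotency genes (7.1e-06 to 0.034) the difference was 0.438 for Nanog minus Sox2 and -0.247 for Nanog minus Tcl1. It was -0.649, -0.665 and -0.474 for Oct4 minus Tbx3, Tcl1 and Mm343880, -0.787, -0.717 and -0.668 for Sox2 minus the same courses, and -0.317, -0.308 and -0.323 for Esrrb minus them. For primed epiblast genes (2e-05 to 0.039) it was 0.571 for Nanog minus Oct4 and -0.472 for Nanog minus Tcl1. It was -0.819, -0.888, -1.07 and -0.899 for Oct4 minus Esrrb, Tbx3, Tcl1 and Mm343880, and -0.828 for Sox2 minus Tcl1. For fibroblast markers (0.0013 to 0.038) it was -0.425, -0.874 and -0.411 for Nanog minus Sox2, Esrrb and Mm343880, and -0.696 for Oct4 minus Esrrb. For mitotic genes (0.013 to 0.036) it was -0.39, -0.495, -0.498 and -0.461 for Sox2 minus Esrrb, Tbx3, Tcl1 and Mm343880. Neuroectoderm genes differed by -0.111 for Oct4 minus Sox2 (adjusted p = 0.021) and germ line genes by -0.387 for Esrrb minus Tcl1 (adjusted p = 0.043).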

How the results depend on the processing

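Array quality weights, leaving out 3 arrays and leaving out day 0 of every course were chosen after seeing the data. The 6 target genes passed under every leave-one-out of days, which their same sign on 8 of 8 days fixed in advance. The cause of the other movements was not tested unless fewer arrays or other genes entered by construction. Low signals limit the folds.

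Without a filter 8 genes passed beyond the empty vector in Tcl1. Quantile normalization gave 22 in Tbx3. With all probe sets, named or not, late differences were 5133 (Nanog), 3761 (Oct4), 5458 (Sox2), 2824 (Esrrb), 2653 (Tbx3), 2134 (Tcl1) and 3831 (Mm343880), changes beyond the empty vector 120 (Tbx3) and 329 (Mm343880), the change with retinoic acid 8400, Sox2 minus Tcl1 5367 and the median of direct differences 3567, with more features tested. A spline with 2 degrees of freedom gave 102 (Oct4), 241 (Sox2), 21 (Tbx3) and 98 (Mm343880) beyond the empty vector and 783 for Esrrb minus Tbx3. Without a spline, on fewer arrays, late differences were 1093 (Esrrb), 815 (Tbx3), 618 (Tcl1) and 1055 (Mm343880), direct differences 940 (Nanog minus Oct4), 813 (Nanog minus Sox2), 609 (Oct4 minus Sox2) and 71 (Esrrb minus Tbx3) with a median of 1447, changes beyond the empty vector 160, 33, 53, 34, 2, 2 and 18 in the order of courses above, and the change of the empty vector 5. A fit of only the courses compared gave 275 (Nanog), 210 (Sox2), 36 (Tbx3) and 45 (Mm343880) beyond the empty vector, 9 for the empty vector, 904 for Nanog minus Sox2 and 233 for Esrrb minus Tbx3. Retinoic acid set against the empty vector on late days gave 7296.

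Array quality weights, whose estimation stopped before reaching its tolerance, gave 275 (Oct4), 600 (Sox2), 1112 (Tbx3), 42 (Tcl1) and 281 (Mm343880) beyond the empty vector. Without Nanog day 5, Sox2 day 6 and Mm343880 day 4 the counts were 140 (Tbx3), 31 (Tcl1) and 469 (Mm343880), and 233 for the empty vector. Without day 0 they were 129, 41, 46, 48, 8, 7 and 39 in the order of courses above, 2793 with retinoic acid and 43 for the empty vector. The median correlation of changes was 0.67 over genes past the test and 0.566 for late differences. Of 49 gene lists past the test 26 passed with an estimated correlation. Reversed values were -0.184 for Bst2 and -0.355 for Pgk1 without Mm343880 day 6 (up to 1.45 and 0.971 without day 5), 0.107 for Foxd3 and 0.088 for Oas1a without retinoic acid day 0 (down to -2.79 and -2.84 without day 6), 0.106 for Foxd3 without day 0, and -0.311 (Esrrb) and -0.447 (Tbx3) for primed epiblast genes beyond the empty vector.

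Leaving out each day in turn gave late differences of 2265 to 3130 (Nanog), 1852 to 2436 (Oct4), 2676 to 3483 (Sox2), 1128 to 1768 (Esrrb), 823 to 1666 (Tbx3), 632 to 1258 (Tcl1) and 633 to 2303 (Mm343880). Beyond the empty vector the ranges were 85 to 672, 36 to 182, 44 to 411, 14 to 220, 2 to 104, 2 to 26 and 5 to 373 in that order, with retinoic acid 1993 to 4647 and for the empty vector 6 to 231. Direct differences ranged from 138 to 482 (Esrrb minus Tbx3), 1073 to 1922 (Nanog minus Oct4), 822 to 1669 (Nanog minus Sox2), 625 to 1228 (Oct4 minus Sox2) and 2225 to 3153 (Sox2 minus Tcl1), with a median of 1561 to 2312. The median correlation of changes was 0.283 to 0.37. Target log2 differences were -1.43 to -1.35 (Esrrb), -2.77 to -2.69 (Nanog), -2.87 to -2.62 (Pou5f1), -2.39 to -2.22 (Sox2), -3.20 to -2.76 (Tbx3) and -1.84 to -1.71 (Tcl1), with 6 to 6 targets past the test. Under the other settings 657 (no spline) to 728 (a pseudocount of 1) of 741 named gene and comparison pairs kept their direction and call. Of these pairs 210 changed their call when some day was left out.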

Other observations

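The tests against retinoic acid day 0, of mixed cells at day 7 and of fibroblasts, and the choice of pairs of courses for swaps, were made after the results were seen. Rhox5, a homeobox gene of the LIF and Stat3 list, was 3.96-fold, 5.72-fold and 2.54-fold higher under Nanog, Oct4 and Sox2 shRNA and 1.79-fold and 2.33-fold lower under Esrrb and Tbx3 shRNA. It was also 1.62-fold higher under Tcl1 shRNA and 1.39-fold higher under Mm343880 shRNA, the latter with adjusted p = 0.1 without empty vector day 4, 0.07 without Mm343880 day 5 and 0.31 without its day 6. Stmn2 was 2.86-fold, 7.16-fold and 3.03-fold lower under Nanog, Oct4 and Sox2 shRNA and did not pass in the other knockdown courses. Psmb8, an immunoproteasome gene, was 4.07-fold, 6.55-fold, 2.92-fold and 3.84-fold higher under Esrrb, Tbx3, Tcl1 and Mm343880 shRNA. It was 1.84-fold higher under Nanog shRNA (adjusted p = 0.028, 0.12 and 0.059 without empty vector days 5 and 6 and 0.18 without Nanog day 5). Psmb8 did not pass under Oct4 or Sox2 shRNA, although without Sox2 day 5 the latter had adjusted p = 0.046. Nnat, an imprinted gene, was 3.49-fold, 5.89-fold and 4.03-fold higher under Sox2, Esrrb and Tbx3 shRNA. It was 1.78-fold and 1.75-fold higher under Tcl1 and Mm343880 shRNA, with adjusted p = 0.052 for both without empty vector day 5, 0.06 for each without its own day 5 and 0.097 without Mm343880 day 6. Nnat did not pass under Nanog or Oct4 shRNA. The interferon response list, which holds Psmb8, did not pass in these courses, with a lowest adjusted p of 0.559.

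Genes that moved in all 7 knockdown courses could reflect the empty vector course alone. Among 68 genes raised in all 7 (chosen without the spline, and 128 with it), the median late log2 difference was 1.57. Their own change from day 0 to day 7 was 1.13 (bootstrap interval over genes 0.903 to 1.43) in the 6 knockdown courses with a day 7 sample. That of the empty vector was 0.147. These values argue against a fall or a constant offset of the empty vector as the whole cause. They cannot exclude an empty vector course that alone lacked a rise shared by transduced cells. The late knockdown samples exceeded the retinoic acid course at day 0, whose labels name no transduction, by 1.11 (0.991 to 1.3). That reference is 1 sample and the genes were chosen on the same late samples, so a difference of the empty vector from such cells stays open. For 20 genes lowered in all 7 (63 with the spline, median -1.28) the same values were -0.321 (-0.645 to -0.156) and -0.446 (-0.722 to -0.00273), and neither explanation can be excluded. A common response to loss of any of these regulators stays open as a hypothesis. All 7 courses carried an shRNA and the reference was an empty vector. A response to carrying any shRNA therefore cannot be told apart from it.

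Pou5f1 signal in the Oct4 course was 0.112 of the empty vector on days 0 to 4 and 0.337 on day 7. A mixture with cells that lack an active shRNA would need a share of 25.3% of such cells. The median day 7 ratio over 31 genes lowered at least 4-fold was 0.28 (0.251 to 0.344), and 11 genes lay below that share. Each ratio compares single arrays, so the spread between arrays can put genes below the share under a mixture too. The median did not lie below the share by more than its interval, so a mixture may account for some or all of the rise and stays open. No biological explanation was tested.

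Tagln and Acta2 rose in the Sox2, Esrrb, Tbx3, Tcl1 and Mm343880 courses by 3.43 and 2.76 on the log2 scale on average. Fibroblasts among the sorted cells are a possible explanation, although the GFP sort would remove feeder cells, and were taken to need a median rise of at least 1 over 10 other fibroblast genes with a low level in the empty vector. The median was 0.53 (bootstrap interval over genes 0.155 to 0.795) in Sox2 and 0.144 (-0.128 to 0.783) in Tbx3. It was 0.41 (-0.0114 to 0.488) in Tcl1 and 0.406 (-0.0409 to 0.737) in Mm343880, so these intervals lay below 1. That cutoff was set after the results were seen and without a fibroblast sample, so it cannot decide the cause. Fibroblasts stay open in these courses, and also in the Esrrb course, where the median was 0.82 (0.322 to 1.08). In that course, against the empty vector, signals went from 750 to 12000 for Tagln, 406 to 1930 for Col1a2, 171 to 398 for Col1a1, 92.9 to 191 for Col3a1 and 77.9 to 94.4 for Dcn.

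Other splits of the samples were made by swapping arrays between the compared courses within a day. Days 4 to 6 have 4 groupings, and days 0, 1 and 4 to 6 have 16, so the groupings are too few for a share under 0.05 (at least 0.25 and 0.0625). Splits that differ only on the remaining days repeat these groupings, so the number of splits as large, given here with the real count and the highest other, is not such a share. For late differences, splits as large were 4 of 100 for Nanog (3059 genes, 3182 in the highest other), 4 for Oct4 (2418, 2688), 6 for Sox2 (3363, 3662), 5 for Esrrb (1767, 2090), 4 for Tbx3 (1611, 2008) and 6 for Tcl1 (1261, 1589), and 4 of 64 for Mm343880 (2062, 2241). For direct differences they were 4 of 100 for Esrrb minus Tbx3 (371, 523), 6 for Sox2 minus Tcl1 (3043, 3354), 7 for Nanog minus Oct4 (1717, 2072), 7 for Nanog minus Sox2 (1534, 1905) and 4 for Oct4 minus Sox2 (1085, 1292). Each of these splits as large kept days 4 to 6 of a course together. Where these days were divided, the highest late counts were 663, 137, 789, 36, 45, 3 and 229 in the order of courses above, and the highest direct counts 1, 897, 466, 725 and 9. Dividing them puts a difference between courses into the spread around the curves, which lowers the counts by construction. These low counts therefore do not weigh against chance. For changes beyond the empty vector, splits as large were 13 of 100 for Nanog (472, 1742), 21 for Oct4 (180, 2407), 23 for Sox2 (366, 2891), 18 for Esrrb (209, 1825), 21 for Tbx3 (73, 2106) and 23 for Tcl1 (18, 953), and 12 of 64 for Mm343880 (159, 1428). The highest of these kept days 4 to 6 together and swapped day 0, day 1 or both against them, which adds an early difference to the late one in place of subtracting it.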
